A study of Mus musculus with 56 samples.

How the data were processed

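Per the labels, gastrocnemius muscle was taken from mice of 20 to 22 weeks that expressed GFP-tagged L10A ribosomal protein under Cre recombinase driven by the Mlc1f promoter. The mice were either controls or carried a floxed Elavl1 gene, which encodes the RNA-binding protein HuR. Per the labels' protocols, total RNA came from whole homogenates by Trizol. Ribosomal RNA came from isolation of tagged ribosomes by a published procedure. Libraries were made from 500 ng of RNA with the Lexogen QuantSeq 3' kit and sequenced as 50 bp forward reads. Per the submitters' processing notes, the authors used UMI-tools, STAR and HTSeq with genome build GRCm39, and DESeq2 1.40.1 in R 4.3.0. The deposited table holds a whole count per gene and library. It was used as deposited, with no correction of the counts.

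Columns were assigned to groups by the codes in the descriptions of the samples, and 0 columns stayed unused. The table held 57010 genes and 5 summary lines of HTSeq, which were left out of library sizes and tests. In ribosomal libraries 64.4 to 77.5% of all counted reads were assigned to genes, 4.82 to 12.5% had no feature, 0.417 to 0.621% were ambiguous and 17.1 to 23.8% were not uniquely aligned. In total libraries these shares were 62.2 to 71.8%, 9.54 to 23.4%, 0.463 to 0.653% and 14 to 18.8%. Gene symbols came from a gene table of GRCm38.p6, which matched 52029 of the identifiers and 97.56% of the counts. From that build only the order of genes around Elavl1 was used, and no coordinates are given. No 2 libraries were identical, and the highest correlation between 2 libraries was 0.9873.

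Genes were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr on the groups, TMM normalization and the quasi-likelihood F-test (glmQLFit and glmQLFTest). Ribosomal and total libraries were fitted apart, each with 4 group means of 7 libraries. Contrasts between RNA types used 1 fit of all 56 libraries with 8 group means. Positive values are higher in labelled knockouts, in ribosomal RNA or in males. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. CPM values were computed from the deposited counts and TMM-scaled library sizes and are given as mean ± SD over 7 libraries. Logarithms for other measures used a prior count of 2.

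For each contrast the text names the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean CPM of at least 5 and a symbol that is not a predicted or clone name. Elavl1 and its paralogs were added, as were up to 4 members of lowest p of each gene list described. Genes named outside this rule are marked as chosen after their values were seen. Some results that this rule covers are not reported here.

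Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The alternatives were camera with an estimated correlation, and fry. The 43 lists were written from general knowledge of pathways and cell types, and 41 held enough measured genes to be tested. Members were counted by the adjusted p over all genes and, where given, as adjusted over the list alone. The samples, contrasts, tests, rule for named genes, gene lists and first set of alternatives were fixed before the data were examined. The alternatives of that set were RLE size factors, no filter beyond 1 count, DESeq2 1.42.0, limma-voom with sample weights, a fit of the 14 libraries compared alone, a fit of all 56 libraries, and the mouse as a block.

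Alternatives added after seeing the data were leaving out the shallowest ribosomal library, leaving out ribosomal libraries under 0.75 M counts, the level of mitochondrially encoded mRNA as a covariate, leaving out 2 libraries that held kidney transcripts, leaving out the 5 total libraries with over 19% of reads outside genes (female control 14, female knockout 9 and male controls 25, 26 and 27), and leaving out each library in turn. Lists of 15 kidney and 16 liver transcripts and a score of the knockout signature were added as well. Group labels were exchanged in 100 splits that kept the real grouping as 1 of them, and genes were counted in each.

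Ribosomal and total libraries of a sex and genotype that share a number in the labels were taken as the same mouse. The mean correlation of their deviations from the group means, over the 500 most variable genes with at least 10 CPM, was 0.0922 in female controls, 0.208 in female labelled knockouts, −0.208 in male controls and 0.0735 in male labelled knockouts. Of all 5040 pairings within a group, 160, 14, 4876 and 516 in the same order gave as high a mean. The values therefore do not back the labelled pairing in male controls and do not settle it in male labelled knockouts. The block rests on the labels. Because the labels give the same number, the fit with the mouse as a block is given for named genes and lists whose call it changes. Counts simulated from the fitted means and spreads with added changes showed the recovery of the tests. With 2-fold changes 71% were called in ribosomal RNA of females, 92% in total RNA of females and 58% in the contrast of RNA types in females. With 4-fold changes these shares were 96%, 100% and 97%.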

Results

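The series holds 56 libraries from gastrocnemius muscle, with 7 mice in each of 4 groups of sex and genotype and a ribosomal and a total library per mouse. Ribosomal libraries held 0.16 to 3.58 M counts (median 1.62) and total libraries 2.43 to 5.85 M (median 3.56). By group, ribosomal depth was 0.423 to 3.06 M in female controls, 0.491 to 1.21 in female labelled knockouts, 0.705 to 2.85 in male controls and 0.16 to 3.58 in male labelled knockouts. Total depth in the same order was 2.82 to 5.16, 2.63 to 3.96, 2.43 to 5.14 and 2.63 to 5.85 M. After filtering, 9098 genes were tested in ribosomal RNA, 12860 in total RNA and 12546 across RNA types. The tagged L10A protein marks ribosomes of muscle fibres, so ribosomal RNA is read as RNA bound to fibre ribosomes and total RNA as RNA of the whole muscle.

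Elavl1, the targeted gene (identifier ENSMUSG00000040028), encodes HuR, which binds AU-rich mRNAs. Its level did not pass the test in either RNA type or sex. The counts come from the 3' end of the transcript and the labels do not give the floxed exons, so the tag may lie outside the deleted part and then checks nothing. The groups are therefore called labelled knockouts. In ribosomal RNA of females Elavl1 stood at 87.65 ± 14.5 CPM in controls and 105.8 ± 20.1 in labelled knockouts (log2 fold change 0.27, standard error 0.149, adjusted p = 0.206). In males the levels were 56.97 ± 8.45 and 66.51 ± 17 CPM (0.29, standard error 0.144, adjusted p = 0.234). In total RNA they were 87.45 ± 17 and 86.48 ± 9.22 CPM in females (−0.01, standard error 0.127, adjusted p = 0.969) and 90.47 ± 17.4 and 81.97 ± 14.4 CPM in males (−0.14, standard error 0.127, adjusted p = 0.477). The mean of both sexes was 0.28 in ribosomal RNA (adjusted p = 0.052) and −0.08 in total RNA (adjusted p = 0.57). The paralogs Elavl2, Elavl3 and Elavl4, which encode the neuronal family members, held 176, 118 and 122 counts over all 56 libraries and were not tested.

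**Figure D1:**
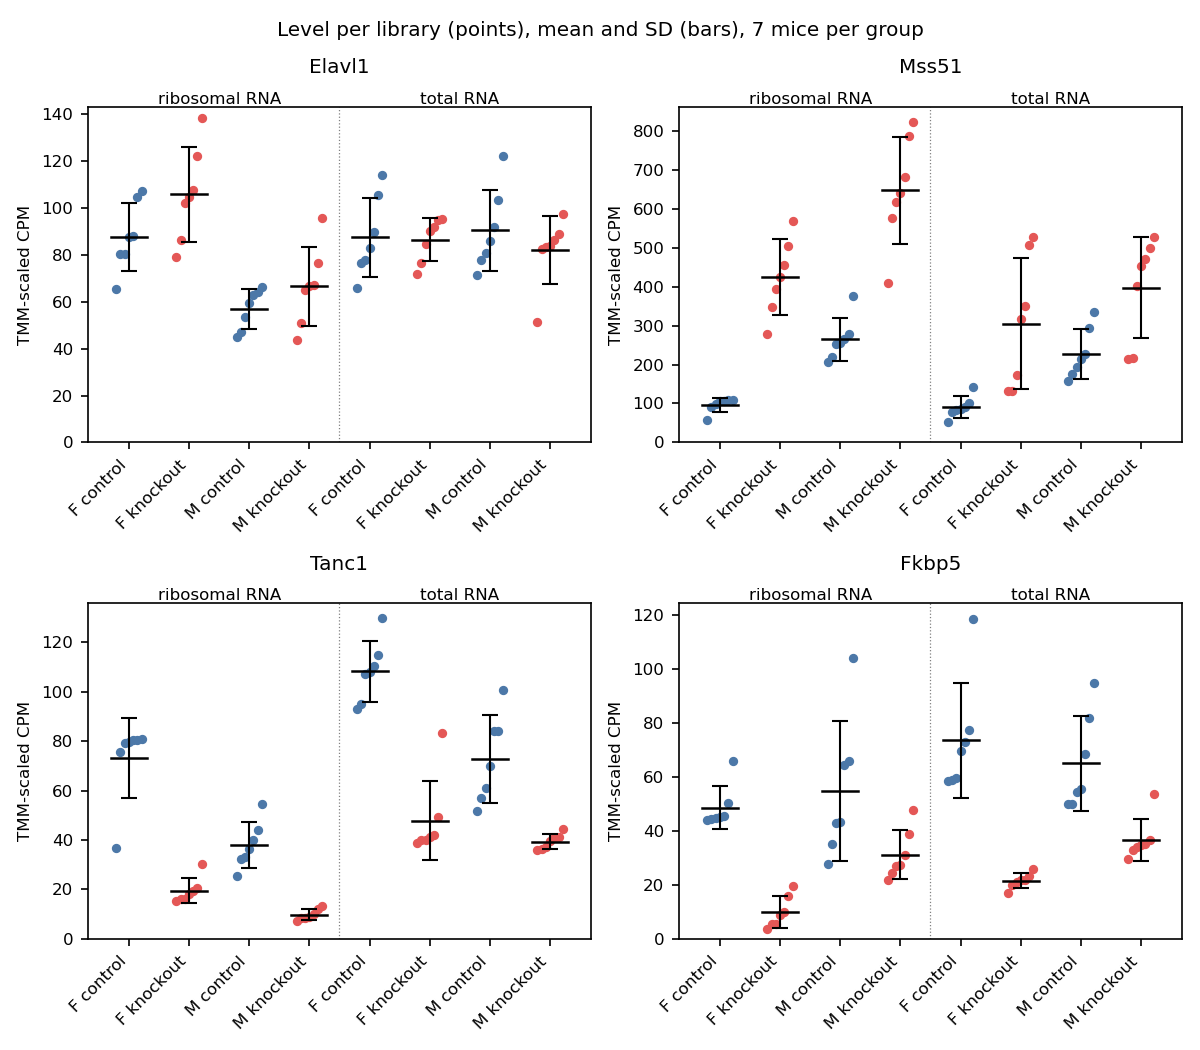
TMM-scaled CPM of Elavl1, Mss51, Tanc1 and Fkbp5 in each library of the 8 groups, with mean and SD. The last 3 genes were chosen after their values were seen.

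Ribosomal RNA of females asks what differs between labelled knockouts and controls in RNA held by tagged ribosomes. Mss51, which encodes a mitochondrial protein of skeletal muscle, rose, and Tanc1, a scaffold protein gene, and Fkbp5, a glucocorticoid-responsive co-chaperone gene, fell. Most fatty acid oxidation genes tested, such as Acat1, fell, and so did the acyl-CoA thioesterase genes Acot1 and Acot2 and Plin5 of the lipid droplet surface. The cell cycle inhibitor Cdkn1a and the atrophy ligase gene Fbxo32 fell as well. Most slow fibre genes tested, such as Myh7, rose. Transcripts of extracellular matrix, endothelium and mitochondria, which tagged fibre ribosomes should hold little of, also rose. Reads outside genes made up 6.53 to 12.5% in these labelled knockouts. They made up 5 to 5.46% in female controls other than 18 and 19, which had 9.31 and 10%. Of 9098 genes 1533 changed, 768 higher and 765 lower, against at most 143 in the other 99 of 100 splits of the labels. The 14 libraries alone gave 936, with 7 of the 20 named genes tested. The mitochondrial covariate, which followed genotype in females, gave 508 with 7 of 20 named genes kept. Leaving out 1 library gave 1125 (without female control 15) to 1764 genes.

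Among the largest rises were those of Alb (3.13, adjusted p = 0.000283), Lin28a (2.87, adjusted p = 5.27e-06), Kcnq1ot1 (2.84, adjusted p = 0.000123), Xist (2.81, adjusted p = 0.000213), Atf3 (2.70, adjusted p = 0.0157), Myh9 (2.67), Myh11 (2.67, adjusted p = 9.28e-06), Meg3 (2.55) and mt-Nd5 (2.50, adjusted p = 0.000837). Alb is the liver albumin gene, Lin28a encodes an RNA-binding protein, and Kcnq1ot1, Xist and Meg3 are long non-coding RNAs kept in the nucleus. The 16 liver transcripts, Alb among them, summed to 12.5 ± 10.3 CPM in controls and 63.6 ± 56.3 in labelled knockouts. In ribosomal RNA of males these sums were 5.1 ± 2.81 and 44.5 ± 51.5. In total RNA they were 134 ± 95.9 and 277 ± 240 in females and 72 ± 76.4 and 269 ± 301 in males. The stress factor gene Atf3 did not pass without female knockout 9 (1.84, adjusted p = 0.106). The largest falls were those of the scavenger receptor gene Stab2 (−3.42, adjusted p = 0.00494), the transcription cofactor gene Dach2 (−2.78), the protease gene Htra4 (−2.29), Aen (−2.23), Fkbp5 (−2.17, standard error 0.308, adjusted p = 8.44e-06), Snhg15 (−2.17), Acot2 (−2.09, adjusted p = 7.3e-05), Iqgap2 (−2.01), Acot1 (−1.94) and Tanc1 (−1.93, standard error 0.176, adjusted p = 3.04e-09). Tanc1 went from 73.25 ± 16.2 to 19.48 ± 5.07 CPM and Fkbp5 from 48.63 ± 7.88 to 9.883 ± 5.86 CPM. Each of the 7 labelled knockouts lay below all 7 controls for both genes. Mss51, chosen after its values were seen, went from 96.71 ± 17.9 to 424.7 ± 96.7 CPM.

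Among gene lists, 22 of 41 were called by camera, and 8 with an estimated correlation. Of 20 fatty acid oxidation genes 0 rose, 14 fell and 6 did not pass (median −0.49, camera adjusted p = 2.12e-11), with Acat1 at −0.73 (adjusted p = 1.15e-05) and Hadh at −0.72. Of 13 PPAR targets 8 fell (median −0.70, camera adjusted p = 5e-07), including Mlycd at −1.18 and Plin5 at −1.34. Of 16 atrophy and ubiquitin genes 8 fell (median −0.40, camera adjusted p = 3.17e-05), with Cdkn1a at −1.90 (adjusted p = 4.15e-07), Map1lc3b at −0.95 and Fbxo32 at −0.90. Of 45 nuclear-encoded oxidative phosphorylation genes 12 fell (median −0.27, camera adjusted p = 4.49e-05, adjusted p = 0.284 with an estimated correlation). Of 13 slow fibre genes 9 rose and 0 fell (median 0.60, camera adjusted p = 1.19e-07, adjusted p = 0.0579 with an estimated correlation), with Myh7 at 2.03 (adjusted p = 3.63e-06), Tnnc1 at 1.01 and Tpm3 at 0.88. All 6 erythroid genes tested rose (median 1.60, camera adjusted p = 5.92e-09), such as Hbb-bt at 1.73 and Hba-a2 at 1.63. Of 28 HuR targets named in the literature 6 rose and 5 fell (median 0.12, camera adjusted p = 0.406), with Ache at 1.56 and Utrn at 1.23 against Cdkn1a and Cat at −0.96.

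Of 19 extracellular matrix genes 16 rose and 0 fell, and 18 rose when adjusted over the list alone (median 1.67, camera adjusted p = 3.23e-21). Fn1 stood at 2.33 (adjusted p = 3.55e-08), Lum at 2.12, Col1a2 at 1.98 and Col1a1 at 1.91. Of 12 fibroblast genes 11 rose (median 1.37, camera adjusted p = 5.87e-15) and of 6 smooth muscle genes 3 rose (median 0.75, camera adjusted p = 0.000272). Of 8 endothelial genes 7 rose (median 1.14, camera adjusted p = 0.000475, adjusted p = 0.226 with an estimated correlation), with Cdh5 at 1.70 and Pecam1 at 1.38. All 7 mitochondrially encoded mRNAs tested rose (median 2.02, camera adjusted p = 1.2e-05, adjusted p = 0.2 with an estimated correlation), mt-Cytb at 2.10 and mt-Co1 at 2.05. The same mRNAs, as a percent of their mean level in total RNA, stood at 8.88 ± 5.04 in female controls, 30.4 ± 16.1 in female labelled knockouts, 7.77 ± 6.82 in male controls and 9.41 ± 13 in male labelled knockouts. Among males control 20 stood at 23 (others 3.7 to 7.2, group median 5.14) and knockout 2 at 38.1 (others 2.58 to 11.5, group median 3.2). In CPM, not scaled to total RNA, the log2 difference was 1.99 in females (exact p = 0.00175 over 3432 arrangements) and 0.139 in males (exact p = 0.844). With this level as a covariate, chosen after the result was seen, the matrix list had a median of 0.74 with 5 of 19 genes higher, the endothelial list 0.05 with 0 genes higher, and fatty acid oxidation −0.69 with 14 of 20 genes lower. The covariate followed genotype in females, so it can take up part of the effect tested, whatever the cause.

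**Figure D2:**
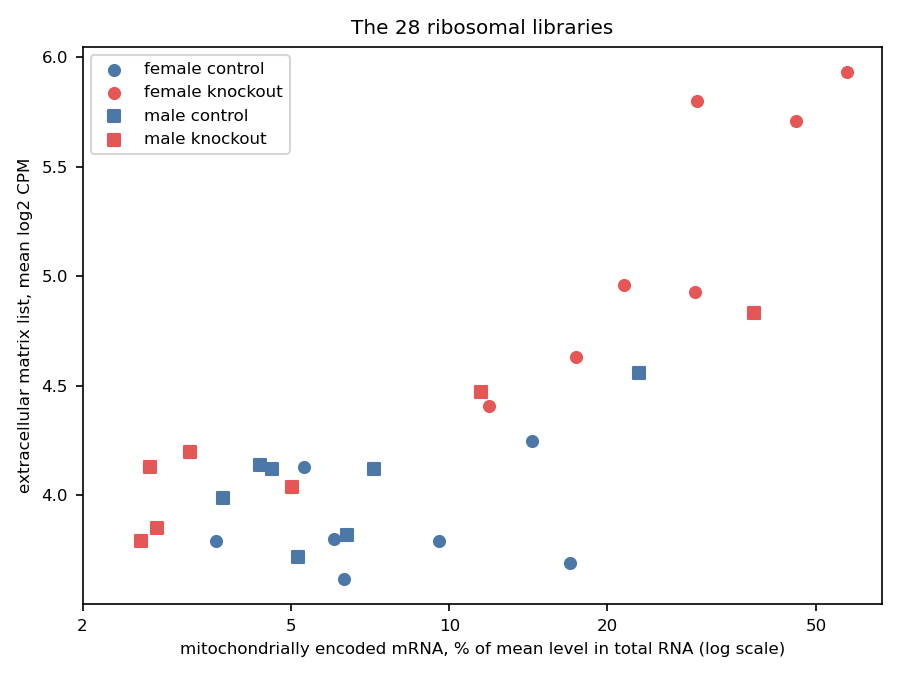
Mitochondrially encoded mRNA in each of the 28 ribosomal libraries, as a percent of its mean level in total RNA, against the mean log2 CPM of the extracellular matrix list. This measure was chosen after the result was seen.

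In ribosomal RNA of males, Mss51 rose and Tanc1, Stab2 and Cdkn1a fell, as they did in females. Genes of polyamine metabolism fell, among them Odc1, which encodes ornithine decarboxylase, Smox, which encodes spermine oxidase, and Amd2. Haemoglobin genes and the haem synthesis gene Alas2 rose. The stress genes Ankrd1 and Atf3 fell, where Atf3 rose in females. Ankrd1 stood at 2820 CPM in male control 20 and at 41.9 to 1220 in the other male controls. For it 1 of 7 labelled knockouts lay below all 7 controls. Of 9098 genes 815 changed, 372 higher and 443 lower, against at most 122 in the other 99 splits, and 1749 with limma-voom. Leaving out 1 library gave 538 (without male knockout 14) to 821 genes.

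The largest rises were those of the transcription factor gene Atoh7 (2.78, adjusted p = 3.9e-05), Cyp4f39 (2.58), Alb (2.44, adjusted p = 0.0221), the calcium-sensing receptor gene Casr (2.23, adjusted p = 2.31e-05), Fgfbp1 (2.09), the retinoic acid hydroxylase gene Cyp26b1 (2.07), Tppp2 (2.06), Vwa3b (1.99), the kinase gene Sik1 (1.88) and Cntnap2 (1.81). Alb did not pass without male control 22 (2.13, adjusted p = 0.0539), male control 23 (2.27, adjusted p = 0.051), male knockout 1 (2.29, adjusted p = 0.0521) or male knockout 14 (1.90, adjusted p = 0.145). The largest falls were those of Stab2 (−3.06, adjusted p = 1.25e-06), Ankrd1 (−2.84, adjusted p = 0.00348), Atf3 (−2.67, adjusted p = 0.023), the metallothionein gene Mt2 (−2.44, adjusted p = 0.00442), Iqgap2 (−2.25), Snhg15 (−2.17), Mfap3l (−2.025), the import receptor gene Tnpo2 (−1.965), Tanc1 (−1.93, standard error 0.168, adjusted p = 1.35e-09) and Odf3l2 (−1.93). Atf3 did not pass without male control 20 (−1.004, adjusted p = 0.295), male knockout 13 (−2.56, adjusted p = 0.0542) or male knockout 14 (−2.62, adjusted p = 0.0546), nor Mt2 without male control 27 (−1.37, adjusted p = 0.0559). Tanc1 went from 37.96 ± 9.47 to 9.814 ± 2.17 CPM and Mss51, chosen after its values were seen, from 265.2 ± 55.2 to 647.3 ± 138 CPM, with each of the 7 labelled knockouts beyond all 7 controls.

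Camera called 5 lists, and 1 with an estimated correlation. Of 14 polyamine and androgen-responsive genes 0 rose, 7 fell and 7 did not pass (median −0.52, camera adjusted p = 0.000328, adjusted p = 0.018 with an estimated correlation). Odc1 stood at −1.27 (adjusted p = 7.86e-05; 34.71 ± 10 to 12.45 ± 5.83 CPM), Smox at −0.97 (475 ± 120 to 242.8 ± 52.6 CPM), Amd2 at −0.96 and Amd1 at −0.67. Of 6 erythroid genes 5 rose (median 1.18, camera adjusted p = 4.39e-07, adjusted p = 0.198 with an estimated correlation), Alas2 at 1.46 and Hba-a1 at 1.29. Of 6 adipocyte genes 2 rose (median 0.45, camera adjusted p = 0.00349, adjusted p = 0.311 with an estimated correlation), Car3 at 0.98. Of 20 fatty acid oxidation genes 3 fell and 7 fell when adjusted over the list alone (median −0.23, camera adjusted p = 0.00812, adjusted p = 0.92 with an estimated correlation), Acadl and Hadha both at −0.46. Of 13 slow fibre genes 3 rose (median 0.25, camera adjusted p = 0.034, adjusted p = 0.961 with an estimated correlation), Tpm3 at 0.56. The matrix list was not called (median 0.14, camera adjusted p = 0.814), and Thbs4 fell (−1.20, adjusted p = 9.8e-05). Nor were mitochondrially encoded mRNAs (median 0.50, camera adjusted p = 0.873), endothelial genes (median 0.18, camera adjusted p = 0.42) or literature HuR targets (median 0.01, camera adjusted p = 0.873).

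Total RNA of females shows what changed in the whole muscle. Mss51, the creatine synthesis gene Gamt and the complex I assembly gene Ndufaf5 rose. Fkbp5, Cdkn1a and the thioesterase genes Acot1 and Acot2 fell. Fatty acid oxidation genes such as Acsl1 and PPAR targets such as Cd36 fell, as did Tbc1d4 and Insr of insulin signalling. The collagen genes Col1a1 and Col1a2 and the tendon gene Tnmd rose. Of 12860 genes 1092 changed, 488 higher and 604 lower, against at most 17 in the other 99 splits. Leaving out 1 library gave 762 (without female knockout 10) to 1284 genes. Total libraries of female knockouts 5, 6 and 12 stood apart, with knockout scores of 0.28, 0.26 and 0.31 against 0.68 to 0.77 in the other 4, where the score follows genes changed in ribosomal RNA of both sexes.

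The largest rises were those of Atoh7 (2.27, adjusted p = 0.0129), Tppp2 (1.89, adjusted p = 0.018), Mss51 (1.75, standard error 0.283, adjusted p = 0.000138), Vwa3b (1.64), Gamt (1.41, standard error 0.204, adjusted p = 4.44e-05), the keratocan gene Kera (1.30), the fatty acid synthase gene Fasn (1.29, adjusted p = 0.0154), Cntnap2 (1.26), Ndufaf5 (1.26, adjusted p = 1.24e-07) and Spon2 (1.25). Tppp2 did not pass without female knockout 1 (1.63, adjusted p = 0.0539) or the 5 libraries with most reads outside genes (1.76, adjusted p = 0.0541), nor Fasn without female knockout 5 (1.06, adjusted p = 0.0501). Mss51 went from 90.43 ± 27.6 to 305.1 ± 168 CPM, with 5 of 7 labelled knockouts above all 7 controls and with female knockouts 5, 6 and 12 at 171.9, 132.8 and 131.3 CPM against 317 to 526.8 in the others. Gamt went from 6.884 ± 1.29 to 18.06 ± 6.68 CPM. The largest falls were those of Htra4 (−2.35, adjusted p = 1.75e-07), Acot1 (−2.21), the acute phase gene Saa1 (−2.18, adjusted p = 0.0123), Arrdc2 (−1.98), Snora30 (−1.85), Stab2 (−1.85, adjusted p = 0.00693), Acot2 (−1.81, adjusted p = 0.000131), Slc25a34 (−1.80), Fkbp5 (−1.76, standard error 0.166, adjusted p = 9.18e-08) and Cdkn1a (−1.58, adjusted p = 0.000354). Fkbp5 went from 73.59 ± 21.2 to 21.54 ± 2.74 CPM and Cdkn1a from 319.9 ± 88.8 to 106 ± 74.9 CPM.

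Camera called 18 lists, and 2 with an estimated correlation. Of 21 fatty acid oxidation genes 0 rose, 12 fell and 9 did not pass (median −0.37, camera adjusted p = 1.78e-12, adjusted p = 0.0582 with an estimated correlation), Acsl1 at −0.53 and Decr1 at −0.39. Of 16 PPAR targets 9 fell (median −0.39, camera adjusted p = 1.88e-08, adjusted p = 0.0628 with an estimated correlation), with Plin5 at −1.21 and Cd36 at −0.57. Of 17 atrophy and ubiquitin genes 7 fell (median −0.36, camera adjusted p = 1.88e-08, adjusted p = 0.0628 with an estimated correlation), Fbxo32 at −1.11. Of 16 insulin signalling genes 5 fell (median −0.21, camera adjusted p = 0.000321, adjusted p = 0.0651 with an estimated correlation), with Tbc1d4 at −0.97 (adjusted p = 2.23e-06; 144.9 ± 19.1 to 73.55 ± 5.96 CPM) and Insr at −0.53. Of 22 matrix genes 14 rose and 0 fell (median 0.54, camera adjusted p = 5.18e-18, adjusted p = 0.0582 with an estimated correlation), Lum at 1.01 and Col1a1 at 0.97. Of 9 tendon genes 3 rose (median 0.64, camera adjusted p = 1.51e-06, adjusted p = 0.133 with an estimated correlation), Tnmd at 1.18. Of 11 cell cycle genes 3 rose (median 0.35, camera adjusted p = 0.000563, adjusted p = 0.0995 with an estimated correlation), Birc5 at 1.27 and Ccnd1 at 0.84. All 6 erythroid genes tested rose (median 0.89, camera adjusted p = 1.03e-09). Mitochondrially encoded mRNAs were not called (median 0.20, camera adjusted p = 0.152), nor were literature HuR targets (median −0.01, camera adjusted p = 0.851). Of 12 endothelial genes 1, Flt1, fell (−0.45; list median −0.17, camera adjusted p = 0.0164, adjusted p = 0.245 with an estimated correlation).

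In total RNA of males Gamt, Mss51 and haemoglobin genes rose and Htra4, Stab2, Odc1 and Tbc1d4 fell. The matrix and fibroblast gene Lum, the tendon gene Tnmd and the ribosomal protein gene Rps2 rose. The RNA-binding protein genes Celf2 and Mbnl1, the clock genes Ciart and Per1 and the heat shock genes Hspa1a and Hspa1b fell. The largest rises were those of kidney transcripts such as Kap, which came mainly from 1 library, and of the urea cycle gene Cps1. Of 12860 genes 1824 changed, 878 higher and 946 lower, against at most 29 in the other 99 splits. Counts fell to 1134 without male control 27, 1167 without male control 26 and 1214 without male knockout 14, and rose to 2127 without male control 22. Male controls 25, 26 and 27 had 19.6, 23.4 and 20.6% of reads outside genes, against 12.4 to 14.7% in the other male controls and 9.78 to 13.9% in male labelled knockouts, and the lowest matrix levels of the group (mean log2 CPM 6.66, 6.4 and 6.48, against 6.89 to 7.23). Without the 5 total libraries above 19%, which hold these 3, 645 genes changed (290 higher, 355 lower), of which 508 were shared, and 9 of 20 named genes kept their call. Limma-voom kept 5 of 20. Total libraries of male knockouts 1 and 12 stood apart, with knockout scores of 0.11 and 0.24 against 0.66 to 0.78 in the other 5, Mss51 at 215.2 and 215.7 CPM against 400.5 to 526.8, and Stab2 at 12.43 and 11.85 CPM against 1.63 to 1.991.

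Among the largest rises were those of Spink1 (3.65, adjusted p = 0.0116), Cyp2j5 (3.27), the kidney endocytic receptor gene Lrp2 (3.17, adjusted p = 0.0336), the kidney androgen-regulated gene Kap (3.17, adjusted p = 0.0255), Fut9 (3.16), the phosphate carrier gene Slc34a1 (3.08), Cltrn (3.02), Acsm2 (2.915) and the urea cycle gene Cps1 (2.68). Without male knockout 6, 8 of these 9 did not pass, with Spink1 1.38 (adjusted p = 0.251), Cyp2j5 1.61 (adjusted p = 0.144), Lrp2 0.56 (adjusted p = 0.716), Kap 0.985 (adjusted p = 0.439), Fut9 1.13 (adjusted p = 0.22), Slc34a1 0.84 (adjusted p = 0.461), Cltrn 0.87 (adjusted p = 0.383) and Acsm2 0.81 (adjusted p = 0.48). Cps1 did not pass without male knockout 14 (2.06, adjusted p = 0.074), and all 9 were lost without the 5 libraries with most reads outside genes (2.24 to 3.21, adjusted p = 0.0961 to 0.19). Leaving out male controls 21, 22, 23, 25, 26 or 27 also ended the call of Lrp2 (2.96 to 3.07, adjusted p = 0.0502 to 0.0647), and leaving out 25, 26 or 27 that of Kap (2.99 to 3.09, adjusted p = 0.0511 to 0.0554). Without male control 20 the values were larger, at 5.015 for Kap, 4.93 for Lrp2, 4.83 for Slc34a1 and 4.63 for Acsm2. Falls were led by Saa1 (−1.95), Ankrd1 (−1.90, adjusted p = 0.0191), Xist (−1.87; 3.318 ± 2.36 to 0.8198 ± 0.464 CPM), Stab2 (−1.76, standard error 0.373, adjusted p = 0.00301), the chemokine gene Ccl2 (−1.74, adjusted p = 0.0364), Lncpint (−1.63), Mchr1 (−1.60, adjusted p = 4.12e-05), Htra4 (−1.53, adjusted p = 1.55e-05), Hspa1b (−1.45, adjusted p = 0.0231) and Hspa1a (−1.43, adjusted p = 0.0158). Xist met the limit of 5 CPM only by its level in females. Lncpint did not pass without the same 5 libraries (−0.505, adjusted p = 0.271). Without male control 20 Hspa1b (−0.69, adjusted p = 0.165) and Hspa1a (−0.67, adjusted p = 0.11) did not pass, nor did Ccl2 without male control 21 (−1.06, adjusted p = 0.164), male control 22 or male knockouts 2, 10, 12, 13 or 14 (−1.525 to −1.72, adjusted p = 0.0558 to 0.0718). Gamt, here chosen after its values were seen, went from 5.918 ± 1 to 17.9 ± 5.56 CPM.

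Camera called 17 lists, and 2 with an estimated correlation. All 6 erythroid genes tested rose (median 1.02, camera adjusted p = 1.35e-12), Alas2 at 1.31 and Hbb-bs at 1.13. All 12 fibroblast genes rose (median 0.52, camera adjusted p = 1.31e-10, adjusted p = 0.154 with an estimated correlation), Dpt at 0.67 and Dcn at 0.66. Of 22 matrix genes 11 rose (median 0.36, camera adjusted p = 3.11e-07, adjusted p = 0.392 with an estimated correlation) and of 9 tendon genes 5 rose (median 0.82, camera adjusted p = 7.01e-05, adjusted p = 0.359 with an estimated correlation), Tnmd at 1.07. Of 58 ribosomal protein genes 13 rose and 0 fell (median 0.22, camera adjusted p = 1.72e-08, adjusted p = 0.494 with an estimated correlation), Rps2 at 0.51 and Rpl15 at 0.48. Without the 5 libraries with most reads outside genes 5 of 12 fibroblast genes rose (median 0.374), 2 of 22 matrix genes (0.14), 2 of 9 tendon genes (0.606), 1 of 58 ribosomal protein genes (0.0853) and all 6 erythroid genes (1.05). Of 19 ARE-binding protein genes 5 fell (median −0.19, camera adjusted p = 0.000265, adjusted p = 0.359 with an estimated correlation), Celf2 at −0.57 and Tia1 at −0.36. Of 14 polyamine and androgen-responsive genes 5 fell (median −0.34, camera adjusted p = 0.00336, adjusted p = 0.0293 with an estimated correlation), Odc1 at −0.996 and Fkbp5 at −0.83. Of 21 fatty acid oxidation genes 5 fell (median −0.14, camera adjusted p = 0.00336, adjusted p = 0.503 with an estimated correlation), Decr1 at −0.34. Of 17 clock genes 6 fell and 1 rose (median −0.28, camera adjusted p = 0.00658, adjusted p = 0.254 with an estimated correlation), Ciart at −1.31 and Per1 at −0.86 against Npas2 at 0.77. Without the same libraries 2 of 19 ARE-binding protein genes fell (median −0.105), 3 of 14 polyamine genes (−0.134), 5 of 21 fatty acid oxidation genes (−0.162) and 4 of 17 clock genes (−0.191). Literature HuR targets were not called (median −0.04, camera adjusted p = 0.544), with Ache at 1.34.

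The mean of both sexes has 14 mice per genotype and can also call changes of 1 sex alone. In ribosomal RNA 1839 genes changed (892 higher, 947 lower), against at most 5 in the other 99 splits and 2862 with all 56 libraries, and in total RNA 3194 (1624 higher, 1570 lower), against at most 80. Leaving out 1 library gave 1646 to 2141 and 2796 to 3721 genes. Ribosomal rises were led by Alb (2.79), Atoh7 (2.55), Lin28a (2.33), Tppp2 (2.28), Cyp4f39 (2.09), Cyp26b1 (2.08), Vwa3b (1.86), Malat1 (1.72, adjusted p = 0.00136; 1.10 without male knockout 2), Mss51 (1.71, standard error 0.110, adjusted p = 1.53e-13) and Myh11 (1.69). Falls were led by Stab2 (−3.24), Dach2 (−2.19), Snhg15 (−2.17), Iqgap2 (−2.13), Tanc1 (−1.93, adjusted p = 1.31e-13), Mt2 (−1.87), Htra4 (−1.85), the sphingosine phosphate transporter gene Spns2 (−1.80), Aen (−1.79) and Cdkn1a (−1.67, standard error 0.158, adjusted p = 1.09e-09). Malat1 passed in females (2.49, adjusted p = 0.00183) and not in males (0.945, adjusted p = 0.301). In total RNA Atoh7 (2.325), Cps1 (2.195), Mup11 (2.06), Cyp2j5 (1.93), Serpina1d (1.75), Tppp2 (1.67), Cyp4f39 (1.66), Mup3 (1.65), Tdo2 (1.54) and Gamt (1.51, standard error 0.146, adjusted p = 1.69e-08) rose most. Saa1 (−2.065), Htra4 (−1.94, adjusted p = 4.93e-10), Stab2 (−1.805), Arrdc2 (−1.53), Cdkn1a (−1.39), Snora30 (−1.36), Fkbp5 (−1.29, standard error 0.114, adjusted p = 3.13e-09), Snhg15 (−1.265), Acot2 (−1.23) and Acot1 (−1.20) fell most. Several of the rises in total RNA, such as those of the liver genes Cps1, Mup11, Serpina1d, Mup3 and Tdo2, are of transcripts that muscle is not known to make. Cyp2j5 did not pass without female knockout 2 (1.68, adjusted p = 0.059) or male knockout 6 (1.11, adjusted p = 0.108), nor Mup3 without female knockout 2 (1.39, adjusted p = 0.0624) or male knockout 14 (1.16, adjusted p = 0.0894). Without the 5 libraries with most reads outside genes Cyp2j5 (1.72, adjusted p = 0.0782), Serpina1d (1.52, adjusted p = 0.0554), Mup3 (1.365, adjusted p = 0.101) and Tdo2 (1.32, adjusted p = 0.0552) did not pass. Camera called 16 lists in ribosomal and 18 in total RNA, and 2 and 3 with an estimated correlation.

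Of 9074 genes tested in both RNA types, 46 were higher and 59 lower in all 4 comparisons within a sex. Those below were picked after their values were seen and are given with their smallest change. Higher in all 4 were Atoh7 (2.265), Vwa3b (1.38), Gamt (1.175), Metrn (0.97), Alas2 (0.95), Cntnap2 (0.92), Ndufaf5 (0.89), Mss51 (0.81), the acetylcholinesterase gene Ache (0.78), Hes1 (0.45) and the slow tropomyosin gene Tpm3 (0.45). Lower in all 4 were Stab2 (−1.76), Htra4 (−1.41), Snhg15 (−1.23), Cdkn1a (−1.20), Arrdc2 (−1.08), Tanc1 (−0.87), Plin5 (−0.81), Fkbp5 (−0.78), Smox (−0.70), the arginine transporter gene Slc7a2 (−0.65), Tbc1d4 (−0.57), the splicing factor gene Rbfox1 (−0.49) and Cpeb3 (−0.30). Between the sexes 130 genes were higher and 136 lower in both in ribosomal RNA, where 31.4 and 37.2 would fall together by chance, and 14 moved in opposite directions. In total RNA 204 were higher and 255 lower in both (33.3 and 44.4 by chance), and 1 moved in opposite directions. Between RNA types 168 were higher and 229 lower in both in females (29.9 and 46.4 by chance), and 153 and 222 in males (22.9 and 37.6 by chance). The chance values take the lists as independent, although ribosomal and total libraries come from the same mice, so those between RNA types are no test. The sexes were compared in 1 fit with a shared spread per gene, so the chance values between them may be too low.

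**Figure D3:**
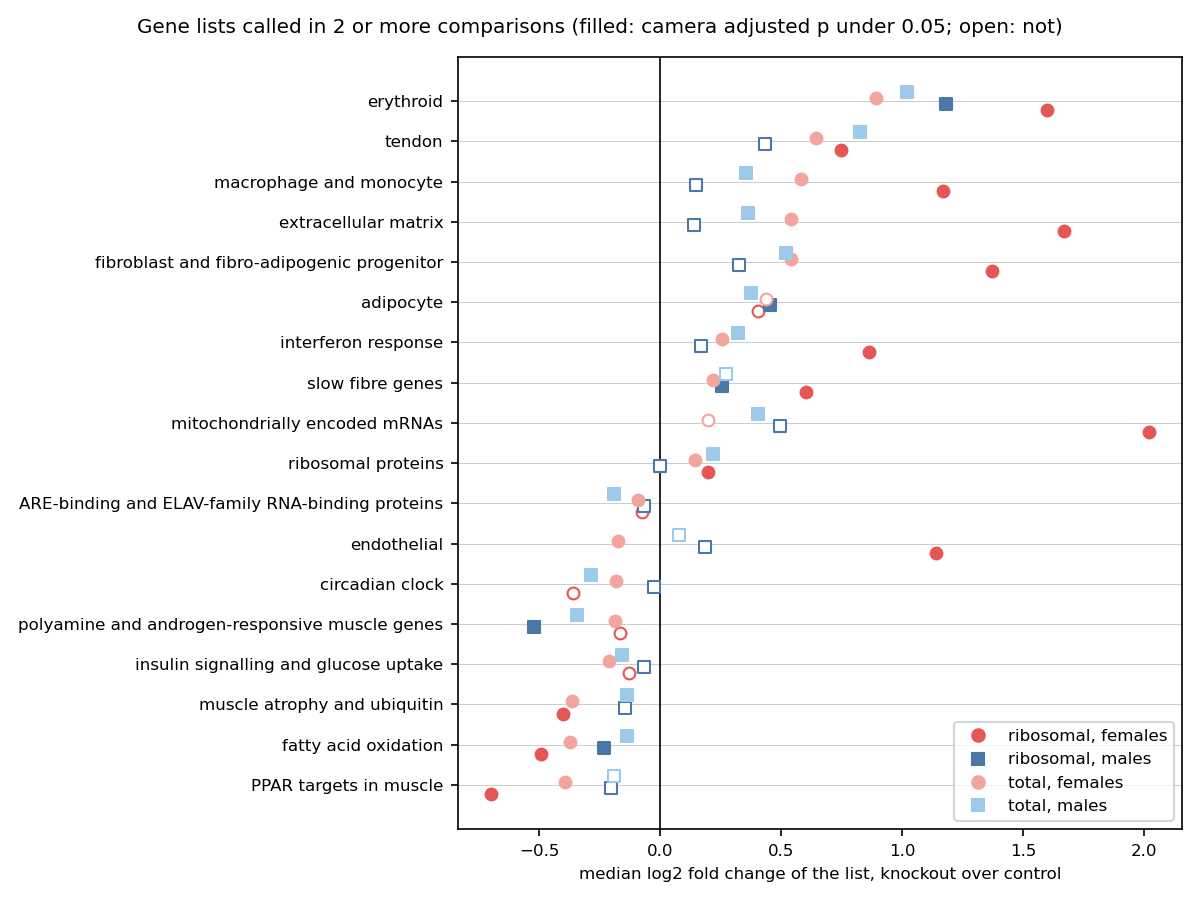
Median log2 fold change of gene lists called in at least 2 of the 4 comparisons within a sex. Filled symbols mark camera adjusted p under 0.05.

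Whether the sexes differ in the effect was tested directly, as the male minus the female change. In ribosomal RNA the male effect was higher for Casr, for Pdk4, which encodes the kinase that restrains pyruvate use, and for the ribosomal protein gene Mrps21 of mitochondria. It was lower for Atf3, Ankrd1, most matrix genes tested, such as Fn1, and mt-Nd6. There 312 genes differed, 172 higher and 140 lower, and 1 of the other 99 splits gave more (374). These splits also broke up the knockout effect common to both sexes, so they do not test the sex difference alone. The count was 626 without a filter, 684 with limma-voom, 829 with all 56 libraries and 23 with the mitochondrial covariate, which kept 1 of 20 named genes. The covariate followed genotype in females but not in males, so this fall does not tell the cause. Leaving out 1 library gave 138 (female control 15), 169 (male knockout 14), 175 (female control 14) and 181 (male knockout 13), or 483 (female control 18) and 498 (female control 19). The male effect was higher for Casr (2.29, adjusted p = 0.0134), Plet1os (2.23, adjusted p = 0.00298), Pdk4 (2.05, adjusted p = 0.0158), Hist2h2be (2.004), Thpo (1.99), Gramd1b (1.95), Mrps21 (1.91), Fgfbp1 (1.78), Ppp3cc (1.77) and Wdr20 (1.71). Among genes with a lower male effect were Atf3 (−5.38, adjusted p = 0.00651), Ankrd1 (−3.71, adjusted p = 0.0158), mt-Nd6 (−3.35, adjusted p = 0.0185), Slc2a3 (−2.87), Csf1r (−2.73), Kcnq1ot1 (−2.63), Myh9 (−2.60, adjusted p = 0.00894), mt-Tl1 (−2.47) and mt-Tm (−2.45). Without female control 15 Hist2h2be (adjusted p = 0.143), Ppp3cc (0.098), Kcnq1ot1 (0.0788), mt-Tl1 (0.0658), Thpo (0.0591), Fgfbp1 (0.0555) and Slc2a3 (0.051) did not pass, nor did Slc2a3 without female knockout 2 (0.0948), Csf1r without female knockout 9 (0.0573) and mt-Tl1 without male knockout 14 (0.0579). Hist2h2be was also lost with any of 5 other libraries left out, Kcnq1ot1 with 5 and Ppp3cc with 8. For Atf3 and Ankrd1 1 library per sex stood far from its group. Atf3 stood at 1020 CPM in male control 20 (others 7.38 to 166) and 770 in female knockout 9 (47.7 to 188). Ankrd1 stood at 2820 CPM (41.9 to 1220) and 1580 CPM (122 to 415) in the same libraries. Leaving out 1 library at a time does not remove both, and a fit without both was not run. Camera called 18 lists and 0 with an estimated correlation. Of 19 matrix genes 11 had a lower male effect (median −1.56, camera adjusted p = 3.62e-16, adjusted p = 0.186 with an estimated correlation), Fn1 at −2.23 and Thbs4 at −1.95. Of 7 mitochondrially encoded mRNAs 1, mt-Nd6, did (list median −1.60, camera adjusted p = 0.0003, adjusted p = 0.3 with an estimated correlation). Of 20 fatty acid oxidation genes 4 had a higher one (median 0.325, camera adjusted p = 0.000762, adjusted p = 0.213 with an estimated correlation), Etfa at 0.83 and Acat1 at 0.67.

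In total RNA no gene passed in edgeR, where 1225 genes had an unadjusted p under 0.05. DESeq2 called 22 genes, the fit without a filter 4, the fit of all 56 libraries 1, that without the 5 libraries with most reads outside genes 3 and limma-voom 0. The genes of lowest p were the small heat shock gene Hspb2 (−0.66), Rasd2 (1.25), Nceh1 (0.70), Cd300lg (0.66; each adjusted p = 0.126) and Ushbp1 (0.85, adjusted p = 0.142). Camera called 10 lists and 0 with an estimated correlation, such as PPAR targets (median 0.30, camera adjusted p = 0.00046, adjusted p = 0.62 with an estimated correlation). Of 2-fold changes simulated in total RNA of females, in genes of at least 5 CPM, 92% were called. Males and the difference between the sexes were not simulated.

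Ribosomal and total RNA of the same mice differed in most genes, which describes what tagging of fibre ribosomes selects. Contractile genes of fast fibres such as Tnnc2, oxidative phosphorylation genes and proteasome genes were higher in ribosomal RNA. Collagens, endothelial genes and RNAs made in mitochondria were lower. Of 12546 genes 10447 differed, 4564 higher and 5883 lower in ribosomal RNA. The other 99 splits gave at most 9. They mixed both RNA types almost evenly within each group, so a low count was near certain and is no test. With DESeq2 the division was 4322 higher and 9378 lower, and with RLE factors 3623 and 7023. The median of all genes moved from −0.133 to −0.344 and −0.346 under these, so small differences depend on the scaling. The highest were Vcp-rs (3.06), Kif28 (3.03), Cfap69 (2.83), Eif3j2 (2.68), Cox6c2 (2.62), the fast troponin C gene Tnnc2 (2.47, adjusted p = 5.31e-26), Ccdc85b (2.46), Lrtm1 (2.46), Taco1 (2.46) and Med29 (2.41). The lowest were mt-Tl2 (−6.65), mt-Ta (−5.78), mt-Tq (−5.04), mt-Tl1 (−4.71), Dnm3os (−4.705), mt-Tv (−4.45), the periostin gene Postn (−4.38), Osmr (−4.35), Srpx (−4.33) and the cathepsin K gene Ctsk (−4.14).

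All 22 matrix genes were lower in ribosomal RNA (median −2.81, camera adjusted p = 9.12e-21, adjusted p = 0.106 with an estimated correlation), Col1a2 at −2.98 and Fn1 at −2.67. All 12 endothelial genes were lower (median −2.23, camera adjusted p = 9.81e-11, adjusted p = 0.114 with an estimated correlation), Cdh5 at −3.29 and Esam at −2.76. All 8 mitochondrially encoded mRNAs were lower (median −2.86, camera adjusted p = 0.000575, adjusted p = 0.295 with an estimated correlation), mt-Nd5 at −4.02 and mt-Co1 at −3.92. Of 45 nuclear-encoded oxidative phosphorylation genes 41 were higher and 0 lower (median 0.72, camera adjusted p = 2.91e-13, adjusted p = 0.131 with an estimated correlation), Ndufb3 at 2.13. Of 15 fast fibre genes 12 were higher and 1 lower (median 1.38, camera adjusted p = 9.32e-06, adjusted p = 0.274 with an estimated correlation), Mybpc2 at 2.16 and Tnnt3 at 1.91. Of 27 proteasome genes 25 were higher (median 0.98, camera adjusted p = 5.36e-10, adjusted p = 0.131 with an estimated correlation), Psmb6 at 1.22. Camera called 24 lists and 0 with an estimated correlation. With the mouse as a block satellite cell genes lost their call (median −1.25, camera adjusted p = 0.0488, and 0.0637 with the block) and erythroid genes gained one (median −0.89, camera adjusted p = 0.0664, and 0.0136 with the block).

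The difference of the effect between ribosomal and total RNA asks where the ribosomal libraries moved apart from the RNA level. In females the long non-coding RNAs Xist and Malat1, the smooth muscle myosin gene Myh11, endothelial genes such as Cdh5 and mitochondrially encoded mRNAs such as mt-Nd5 rose more in ribosomal RNA than in total RNA. The zinc finger gene Zfp729a and the gene Uevld fell more, as did members of the oxidative phosphorylation list. Of 12546 genes 434 differed in effect, 232 higher and 202 lower, against at most 320 in the other 99 splits, and 261 with the mouse as a block (168 higher, 93 lower; 195 calls lost and 22 gained). The splits also broke up the knockout effect common to both RNA types, so they do not test this difference alone. With the mitochondrial covariate, which followed genotype in females, 10 genes passed. The division was 354 and 144 with DESeq2 and 285 and 118 with RLE factors. The effect was higher in ribosomal RNA for, among others, Dnm3os (3.93, adjusted p = 0.0149), Kcnq1ot1 (3.075), Lncpint (2.93), Xist (2.93, adjusted p = 0.000161), Npy1r (2.91), Inhba (2.88), Myh11 (2.77, adjusted p = 9.47e-05), Mall (2.64) and Malat1 (2.505, adjusted p = 0.00947). Malat1 stood at 376.8 ± 213 and 2061 ± 1460 CPM in ribosomal RNA of controls and labelled knockouts and at 3023 ± 612 and 2871 ± 1280 CPM in total RNA. It was lower for Map10 (−2.46), Mrps21 (−1.75) and the iron-sulfur assembly gene Ciao2b (−1.56), and without the block only for Zfp729a (−2.16, blocked adjusted p = 0.0582), Uevld (−1.88, 0.111), Gtf2h3 (−1.82, 0.0527), Tmem29 (−1.69, 0.0593), Nagpa (−1.62, 0.108), Kazald1 (−1.56, 0.0554) and Parp12 (−1.545, 0.11).

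Camera called 17 lists in this female contrast, and 3 with an estimated correlation, of which 0 passed with the mouse as a block (adjusted p = 0.058 for Schwann cell genes and 0.0757 for endothelial and smooth muscle genes). Of 12 endothelial genes 6 had a higher effect in ribosomal RNA (median 1.15, camera adjusted p = 4.39e-11), Cdh5 at 1.81 and Esam at 1.23. Of 8 Schwann cell genes 3 were higher (median 1.27, camera adjusted p = 1.35e-07), and of 10 smooth muscle genes 3 (median 0.58, camera adjusted p = 1.33e-05), Notch3 at 1.80. Of 22 matrix genes 8 were higher (median 0.93, camera adjusted p = 3.63e-15, adjusted p = 0.0694 with an estimated correlation), Fn1 at 1.69. Of 8 mitochondrially encoded mRNAs 5 were higher (median 1.73, camera adjusted p = 5.77e-08, adjusted p = 0.16 with an estimated correlation), mt-Nd5 at 2.07 and mt-Co1 at 1.71. Of 45 oxidative phosphorylation genes 3 were lower, and 19 when adjusted over the list alone (median −0.33, camera adjusted p = 6.42e-10, adjusted p = 0.254 with an estimated correlation), Ndufa8 at −0.75.

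In males the knockout effect differed between RNA types in few genes. It was higher in ribosomal RNA for the protein kinase gene Rock1 and the splicing gene Srek1, and lower for Tanc1, the matrix gene Thbs4 and the interleukin receptor gene Il1r1. In all 16 of 12546 genes differed in effect, 4 higher and 12 lower, against at most 8 in the other 99 splits, and 12 with the mouse as a block (5 higher, 7 lower). Here too the splits broke up the knockout effect common to both RNA types, so they do not test this difference alone. DESeq2 called 48 genes (20 higher, 28 lower), the fit without a filter 53, limma-voom 37, that without libraries under 0.75 M counts 27 and that without the 5 total libraries with most reads outside genes 7. Rock1 stood at 1.265 (standard error 0.179, adjusted p = 2.52e-05), Srek1 at 1.07 (adjusted p = 0.0244) and Zkscan3 at 1.125 (adjusted p = 0.0444, blocked 0.137). The effect was lower for Il1r1 (−1.58, adjusted p = 0.0153), Ggh (−1.49), Thbs4 (−1.48, adjusted p = 0.00668), Scpep1 (−1.17, adjusted p = 0.00232), Tanc1 (−1.09, adjusted p = 0.0211), Pam (−1.09) and Fam3c (−1.025), and, without the block only, Os9 (−1.23, blocked adjusted p = 0.0726), Tspan5 (−1.12, 0.136) and Tmem47 (−0.86, 0.136). Without those 5 libraries Srek1 (0.85, adjusted p = 0.176), Zkscan3 (0.89, 0.236), Thbs4 (−1.19, 0.0539), Ggh (−1.35, 0.0881), Fam3c (−0.89, 0.148), Os9 (−1.135, 0.0676), Tspan5 (−1.165, 0.0676) and Tmem47 (−0.80, 0.145) did not pass. Of 58 ribosomal protein genes 0 differed singly (median −0.26, camera adjusted p = 1.84e-08, adjusted p = 0.766 with an estimated correlation), and 7 lists were called, 0 with an estimated correlation.

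Male and female controls were compared as the background of the sex contrasts. Genes of the Y chromosome and of polyamine metabolism, Amd1, Amd2, Odc1 and Smox, were higher in males, as was the growth hormone signalling inhibitor Cish in ribosomal RNA. The slow fibre genes Myh7 in ribosomal RNA and Tnni1 in total RNA, the cardiac actin gene Actc1 and the adenylate kinase gene Ak4 were lower in males. In ribosomal RNA 694 genes differed (387 higher, 307 lower), against at most 292 in the other 99 splits, 1874 with limma-voom, and 518 to 1289 (without male control 20) with 1 library left out. In total RNA 1119 differed (611 higher, 508 lower), against at most 175, and 892 to 1088 with 1 library left out. Higher in ribosomal RNA of males were Uty (7.695), Eif2s3y (7.11), Ddx3y (6.55), the zinc transporter gene Slc30a2 (4.335), Odf3l2 (3.90), Amd2 (3.15), Amd1 (3.145), Npnt (3.08), Cish (3.03) and Actr3b (2.58), and lower were Zfp385a (−2.16), Gnmt (−2.09), Rhpn2 (−1.98), Padi1 (−1.815), Ak4 (−1.79), Cdo1 (−1.78), Cyp4f39 (−1.735), Selenbp1 (−1.69), Actc1 (−1.60) and Aebp1 (−1.56). Padi1 did not pass without female control 16 (−1.49, adjusted p = 0.0518). In total RNA Kdm5d (6.44), Uty (6.19), Ddx3y (5.84), Eif2s3y (5.55), Slc15a5 (4.31), Slc30a2 (3.48), Odf3l2 (3.13), Amd2 (2.85), Ccl2 (2.75) and Amd1 (2.66) were higher, and Xist (−6.71), Slc1a2 (−2.44), Syt1 (−1.89), Pla2g5 (−1.82), Actc1 (−1.73), Ces1d (−1.56), Ak4 (−1.55), Casr (−1.49), Stc2 (−1.48) and Unc13c (−1.47) lower. Syt1 did not pass without female control 14 (adjusted p = 0.053) or the 5 libraries with most reads outside genes (−1.80, adjusted p = 0.0667).

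Of 14 polyamine and androgen-responsive genes 7 were higher in ribosomal RNA of males (median 0.47, camera adjusted p = 1.61e-16), Odc1 at 2.07 and Smox at 1.99, and 7 in total RNA (median 0.34, camera adjusted p = 9.38e-09). Amd1 stood at 22.1 ± 6.7 CPM in ribosomal RNA of female controls and 202.2 ± 48.8 CPM in male controls. Of 13 slow fibre genes 5 were lower in ribosomal RNA (median −0.42, camera adjusted p = 0.000315, adjusted p = 0.507 with an estimated correlation), Myh7 at −1.32, and 8 in total RNA (median −0.70, camera adjusted p = 1.61e-07, adjusted p = 0.275 with an estimated correlation), Tnni1 at −1.04. Of 16 atrophy genes 6 were lower in ribosomal RNA of males (median −0.36, camera adjusted p = 0.000315), Cdkn1a at −1.27. Camera called 9 lists in ribosomal RNA and 11 in total RNA, and 3 and 2 with an estimated correlation.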

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

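All tests of explanations here were chosen after the result was seen, apart from the rank correlation across genes and the split counts of the 2 contrasts between RNA types in labelled knockouts.

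Single libraries lay far from the other 6 of their group in 36 of 132 sets of values tested. The 6.6 that would by chance takes the sets as independent and picked without the data. They were not, since Kap is also in the kidney list, Alb in the liver list, and the genes came from the results. So 6.6 is no measure of chance here. Female control 18 had a ribosomal knockout score of 0.09 (others −0.05 to 0.01). Female control 19 had 58.7 CPM of Mss51 (90.5 to 109) and 36.7 of Tanc1 (75.7 to 80.9) in ribosomal RNA. Female control 21 had 65.9 CPM of Fkbp5 in ribosomal RNA (44 to 50.2) and 119 in total RNA (58.4 to 77.3), with 13.1 of Stab2 (5.45 to 7.7) and 34.4 of Acot1 (2.57 to 13.4) in total RNA. Female knockout 9 had 30.2 CPM of Tanc1 (15.5 to 20.6), 1580 of Ankrd1 (122 to 415) and 770 of Atf3 (47.7 to 188) in ribosomal RNA. In total RNA it had 83.3 of Tanc1 (38.9 to 49.4), 230 of Atf3 (18 to 66.7) and 5510 of Malat1 (1650 to 3310).

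Among males, control 20 had mitochondrially encoded mRNA at 23% of its level in total RNA (others 3.7 to 7.2), with 2820 CPM of Ankrd1 (41.9 to 1220), 1020 of Atf3 (7.38 to 166), 11.7 of Kap (0.291 to 2.25), 13.6 of Xist (0.291 to 1.28) and 994 of Malat1 (181 to 354) in ribosomal RNA. Its total library had 338 CPM of kidney list genes (175 to 215), 192 of Atf3 (5.98 to 68.1) and 66.9 of Kap (1.39 to 9.01). Male control 21 had 377 CPM of Mss51 in ribosomal RNA (208 to 279) and male control 25 had 8.08 of Xist in total RNA (0.632 to 3.84). Male knockout 1 had 52.2 CPM of Atf3 (14.6 to 24.9) and 148 of Kap (0 to 7.04) in ribosomal RNA. Male knockout 2, the shallowest ribosomal library, had 146 CPM of liver list genes (6.91 to 63.8), 29.2 of Alb (0.469 to 8.99), 21.9 of Xist (0 to 1.71), 3790 of Malat1 (202 to 493) and mitochondrially encoded mRNA at 38.1% (2.58 to 11.5), and 51.4 of Elavl1 in total RNA (82.3 to 97.6). Male knockout 6 had 1950 CPM of kidney list genes (251 to 412) and 713 of Kap (3.4 to 52.5) in total RNA. Male knockout 10 had 53.8 of Fkbp5 (29.6 to 36.6) and male knockout 14 had 169 of Alb (10.5 to 73.8) in total RNA.

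The sexes differed in the knockout effect in ribosomal RNA for 312 genes, by a direct test. Among the genes of largest difference, male minus female, were Casr (2.29), Plet1os (2.23), Pdk4 (2.05), Hist2h2be (2.0), Thpo (1.99), Gramd1b (1.95), Mrps21 (1.91), Fgfbp1 (1.78), Ppp3cc (1.77) and Wdr20 (1.71), and Atf3 (−5.38), Ankrd1 (−3.71), mt-Nd6 (−3.35), Slc2a3 (−2.87), Csf1r (−2.73), Kcnq1ot1 (−2.63), Myh9 (−2.60), mt-Tl1 (−2.47) and mt-Tm (−2.45). Lists with a higher male effect were fatty acid oxidation (median 0.33), PPAR targets (0.41), oxidative phosphorylation (0.24), glycolysis (0.18) and atrophy (0.27). Those with a lower one were mitochondrially encoded mRNAs (−1.60), matrix (−1.56), Schwann cell (−1.33), fibroblast (−1.03), endothelial (−0.98), macrophage (−0.79), tendon (−0.70), smooth muscle (−0.55), fast fibre (−0.44), calcium handling (−0.42), unfolded protein response (−0.39), slow fibre (−0.37) and myofibre genes (−0.28). In total RNA the lists were PPAR targets (0.30), atrophy (0.25), endothelial (0.24), fatty acid oxidation (0.18) and ribosomal proteins (0.05) on the higher side, and immediate early (−0.45), cell cycle (−0.40), heat shock (−0.29), matrix (−0.20) and unfolded protein response genes (−0.20) on the lower. Of the 28 lists 0 passed with an estimated correlation (adjusted p = 0.186 or more).

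Transcripts of non-fibre cells and of mitochondria were higher in ribosomal RNA of female labelled knockouts. Without libraries under 0.75 M counts the matrix list kept a median of 1.53. This cannot decide on shallow libraries as the cause, since depth stayed apart by genotype. The female labelled knockouts left held 0.937 to 1.207 M counts and the female controls left 1.516 to 3.059 M. More endothelial RNA in the muscle was argued against by the endothelial list in total RNA, at −0.17 with 0 of 12 genes higher. Matrix genes also rose in total RNA (14 of 22, median 0.54), so more matrix RNA in the muscle is not excluded. RNA not bound to tagged ribosomes stays open: the first test, Spearman's rho across 9098 genes between the effect and the total-over-ribosomal ratio of male controls, had bounds set before of at least 0.3 if it were the cause and under 0.1 if not, and gave 0.09 (bootstrap of 1000 draws, 95% 0.069 to 0.111), under the bound but within its spread (0.23 in males, 0.212 to 0.25). That bound was a poor one, since a share c of unbound RNA moves mainly genes whose ratio exceeds about 1/c, so 8 ranges of the ratio and 2 rho values per sex were then looked at and a 4-fold limit was picked from them: of 252 genes above it 133 were higher and 0 lower, 52.8% against 8.44% of all genes, where males had 7 higher and 1 lower of 232 genes. At the other end, of 46 genes with a log2 ratio of −2 or less 3 were higher and 0 lower in females (median 0.26). Of 1086 genes with a log2 ratio of −2 to −1 100 were higher and 68 lower (median 0.08). Unbound RNA alone would lower such genes relative to the rest, so these values do not follow from it. In the 7 female labelled knockouts the matrix mean rose with mitochondrially encoded mRNA (r = 0.906, exact p = 0.00516; rho = 0.929, exact p = 0.00675; r = 0.798 without the 2 libraries farthest from the median), so unbound RNA may cause much of this pattern, but a limit picked from the data cannot decide it, and ribosome binding in other cells cannot be told apart from it.

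Kidney transcripts were higher in total RNA of male labelled knockouts. Kidney RNA in 1 library could give these calls: 6 of 7 kidney list genes were called with all libraries and 1 without male knockout 6, and their median went from 3.08 to 0.81. That library was left out for its high kidney sum, so a loss of calls was likely from the start. The calls rested mainly on it, but this cannot decide on the source. Expression of kidney genes in the muscle stays open, since 3 of 7 male labelled knockouts lay above the highest male control in summed kidney CPM. Aqp1 and Kap, 2 of the 15 list genes, reached a mean of 5 CPM in female control totals, where Kap ran from 0.96 to 51.66 CPM.

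The knockout score, the slope over 75 genes changed at least 2-fold the same way in ribosomal RNA of both sexes (74 in the total fit), spread widely over total libraries of labelled knockouts: 0.66 to 0.78 in 9 of them, 0.28, 0.26 and 0.31 in female knockouts 5, 6 and 12, and 0.11 and 0.24 in male knockouts 1 and 12. An exchange with a control library of this series was argued against by the highest score of a control total library, 0.09, as no control is out of place. Fewer recombined fibres in the piece used for total RNA would weaken all genes alike, but the 22 genes of the score that fall kept a median of 0.93 to 0.99 of their fall in female knockouts 5, 6 and 12 (lower ends of the bootstrap 95% ranges 0.67 to 0.77), with Tanc1 at 39.89, 38.93 and 41.22 CPM and Stab2 at 4.776, 3.018 and 2.425 (0.7645 to 2.235 in the other female labelled knockouts, 5.454 to 13.09 in female controls), which argues against it there. In male knockouts 1 and 12 it stays open, since they kept 0.77 and 0.73 with 95% ranges that began at 0.44 and 0.35, with Tanc1 at 40.78 and 41.12 CPM against 35.9 to 44.37 in the other male labelled knockouts, but Stab2 at 12.43 and 11.85 CPM against 1.63 to 1.991 there and 12.81 to 18.86 in male controls. In the order female 5, 6 and 12 and male 1 and 12, these libraries also had Rpl10a at 1.12, 1.81, 1.21, 2.33 and 2.79 CPM (other labelled knockout totals 3.53 to 13.3), Gt(ROSA)26Sor at 3.09, 14.5, 1.21, 2.33 and 2.09 (1.27 in female knockout 9, 23.1 to 33.1 in the rest) and mitochondrially encoded mRNA at 50870, 45910, 60010, 58690 and 58090 (24290 to 45250), and no biological explanation was tested.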

How the results depend on the processing

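The settings called added were chosen after the data were seen. Of 1998 values of named genes under these settings 1821 kept their direction and their side of the limit, 170 were weaker, 7 stronger and 0 reversed. Named genes that were not tested under a setting are not in these counts. With the 14 libraries alone 7 of 20 named genes were tested in ribosomal RNA of females and 13 of 20 in total RNA of males. The weaker ones were 3 with RLE factors, 6 without a filter, 9 with DESeq2, 29 with limma-voom, 6 with the 14 libraries alone, 1 with all 56 libraries and 11 with the mouse as a block. With added settings they were 0 without the shallowest library, 12 without ribosomal libraries under 0.75 M counts, 54 with the mitochondrial covariate, 14 without the 2 kidney libraries and 25 without the 5 total libraries with over 19% of reads outside genes. The covariate kept 7 of 20 named genes in ribosomal RNA of females, 1 of 20 in the sex difference there and 0 of 20 in the RNA type difference in females. It followed genotype in females, so it can take up part of the effect tested in these contrasts, whatever the cause. Limma-voom kept 5 of 20 in total RNA of males. Of 2-fold changes simulated in genes of at least 5 CPM 71% were called in ribosomal RNA of females, 92% in their total RNA and 58% in the contrast of RNA types, where depth was not separated from the spread between mice.

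Counts of genes moved by over 1.5 times as follows, and the cause was not tested. In ribosomal RNA of females 1533 became 508 with the covariate (377 shared) and 936 with 14 libraries alone (906 shared, 7035 instead of 9098 genes tested). In ribosomal RNA of males 815 became 1749 with limma-voom (811 shared), and for the mean of both sexes 1839 became 2862 with all 56 libraries (1759 shared). The sex difference in ribosomal RNA went from 312 to 626 without a filter, 684 with limma-voom, 829 with 56 libraries and 23 with the covariate (261, 303, 297 and 20 shared). In total RNA it went from 0 to 4 without a filter, 22 with DESeq2, 1 with 56 libraries and 3 without the 5 libraries. In total RNA of males 1824 became 645 without these (508 shared), which also leaves 4 male controls. The RNA type difference in females went from 434 to 10 with the covariate (5 shared) and 261 with the mouse as a replicate block (239 shared). In males it went from 16 to 53 without a filter, 48 with DESeq2, 37 with limma-voom and 27 without libraries under 0.75 M (13, 16, 16 and 16 shared), and 7 without the 5 libraries (5 shared). Male against female controls in ribosomal RNA went from 694 to 1874 with limma-voom (689 shared). The block ended 195 calls and added 22 in females, ended 6 and added 2 in males (16 to 12, within 1.5 times), and ended 167 and added 91 between RNA types. Of the named genes and lists it changed no call beyond those given with blocked values.

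Elavl1 in total RNA turned to 0.018 in females (adjusted p = 0.937) and 0.000 for the mean of both sexes (adjusted p = 0.998) with limma-voom, and without the 5 libraries to 0.036 (adjusted p = 0.886), 0.034 in males (adjusted p = 0.921) and 0.035 for the mean (adjusted p = 0.823), and passed neither way. In ribosomal RNA its mean over both sexes, 0.280 (adjusted p = 0.052), passed at 0.289 with RLE factors (adjusted p = 0.0419), 0.278 with limma-voom (adjusted p = 0.0254) and 0.414 with the covariate (adjusted p = 0.0148), and the cause was not tested. Leaving out 1 library at a time gave counts of 1125 to 1764 and 538 to 821 in ribosomal RNA of females and males, 762 to 1284 and 1134 to 2127 in total RNA, 1646 to 2141 and 2796 to 3721 for the means, 138 to 498 and 0 to 0 for the sex differences, and 518 to 1289 and 892 to 1088 for male against female controls.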

Other observations

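The tests of this part were chosen after the results were seen, and so were the split counts, apart from those of the 2 contrasts between RNA types in labelled knockouts.

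Camera called further lists. In ribosomal RNA of females some interferon response genes rose (3 of 6, median 0.86, camera adjusted p = 0.0203, adjusted p = 0.134 with an estimated correlation), as did macrophage genes (3 of 4, median 1.17, camera adjusted p = 0.00436, adjusted p = 0.0634 with an estimated correlation) and tendon genes (2 of 3, median 0.75, camera adjusted p = 0.00968). In total RNA of males interferon response genes such as Psmb8 (0.68) and Gbp2 (0.89) rose (3 of 15, median 0.32, camera adjusted p = 0.0067, adjusted p = 0.494 with an estimated correlation), as did adipocyte genes such as Plin1 (0.70; 3 of 9, camera adjusted p = 0.00828, adjusted p = 0.494 with an estimated correlation). Of 8 mitochondrially encoded mRNAs 2 rose there (median 0.41, camera adjusted p = 0.00321, adjusted p = 0.494 with an estimated correlation), mt-Nd5 at 0.59, and their sum was highest in male knockouts 1 and 12, which also had the lowest knockout scores (58690 and 58090 CPM, against 27820 to 43070 in the other male labelled knockouts). Without the 5 total libraries with most reads outside genes 0 of 15 interferon response genes, 2 of 9 adipocyte genes and 1 of 8 mitochondrially encoded mRNAs rose there. In ribosomal RNA of males the clock list was not called (camera adjusted p = 0.814), though Arntl rose (1.10, adjusted p = 0.000136) and Bhlhe41 fell (−0.64). Mstn, the myostatin gene, fell there (−1.17, adjusted p = 0.0223). Adipocyte genes were lower in total RNA of male than of female controls (4 of 9, median −0.51, camera adjusted p = 0.00118, adjusted p = 0.397 with an estimated correlation), Adrb3 at −1.62 and Retn at −1.19, and macrophage genes higher (4 genes, median 0.55, camera adjusted p = 0.00118, adjusted p = 0.579 with an estimated correlation).

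Across genes the changes of females and males correlated at r = 0.367 (rho 0.26) in ribosomal RNA. Genes differing between the sexes in ribosomal and total RNA of controls overlapped in 191 higher and 124 lower genes, against 19.7 and 14.7 by chance, taking the lists as independent although the mice are the same. In controls of both sexes Tnnc2 was far higher in ribosomal RNA, such as 31630 ± 20000 against 7434 ± 650 CPM in females.

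Same-numbered ribosomal and total libraries of male controls did not deviate together (mean r = −0.208). Numbers that run in opposite order in the 2 RNA types could explain this; that order gave 0.157, and 442 of 5040 pairings gave as much, so the order is not settled. In male labelled knockouts same-numbered libraries had a mean r of 0.0735, which 516 of 5040 pairings reached, so their pairing is not settled either. Strain DNA carried along with the targeted allele could change genes near Elavl1. Among the 50 nearest protein-coding genes in the gene order of GRCm38.p6, 9 of 31 tested were called in total RNA for the mean of both sexes, 29% against 24.8% of all genes (Fisher's exact p = 0.54), which leaves it open. In the other comparisons the share lay above that of all genes in ribosomal RNA of females (23.8% against 16.8%), total RNA of females (9.68% against 8.49%) and the ribosomal mean (23.8% against 20.2%), and below it in ribosomal (4.76% against 8.96%) and total RNA of males (12.9% against 14.2%).

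Exchanged labels bear on how many calls the grouping gives. The real grouping gave the most genes in 11 of 13 comparisons, where 1 of 100 splits, the real one, reached its count: 1533, 815 and 1839 genes in ribosomal RNA of females, males and their mean (highest other 143, 122 and 5), 1092, 1824 and 3194 in total RNA (17, 29 and 80), 10447 between RNA types (9), 434 and 16 for the RNA type difference of effects in females and males (320 and 8), and 694 and 1119 between controls of the sexes (292 and 175). Splits between RNA types mixed both types almost evenly within each group, so their low counts are no test. For the sex difference in ribosomal RNA 2 of 100 splits reached 312 genes (highest other 374). Splits for this difference and for the RNA type differences of effects also broke up the knockout effect itself. They therefore do not test those differences alone. In total RNA, with 0 genes called, all 100 of 100 splits reach that count by construction (highest other 112), so the splits test nothing there.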
